A study of Mus musculus with 12 samples.

How the data were processed

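Total liver RNA of 12 samples in 6 groups of 2 had been hybridised to Affymetrix mouse arrays, and the deposited value table gives 1 signal intensity per probe set and array on a linear scale. How the authors computed these deposited intensity values, including the software, background correction and scaling, is not given in the sources used here. The values behaved as already scaled: the 2% trimmed mean per array differed by at most 1.097-fold and the log2 medians by 0.09, so they were used as deposited. Groups came from the sample labels, which give the genotype, the injection and the replicate number.

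Of 12488 probe sets, 66 control probe sets were left out. Intensities below 33.0, the 25th percentile over all arrays, were set to that floor and log2 was taken. A probe set was tested if it lay above the floor on at least 2 arrays, which left 9641. Changes of genes near the floor are understated, and differences between 2 responses may be understated or overstated. A gene at the floor on all arrays of a group has only a lower bound on its fold. Such a group also shows no spread, so the SE and p of that gene may be too small. The platform annotation lists 11251 probe sets, 10855 with 1 gene symbol and 396 with several; 1193 probe sets had no symbol. Of those with 1 symbol 10839 matched a current gene by Entrez identifier and 0 symbols needed an update. No gene was named from a probe set with several symbols. For gene lists the probe set with the highest mean over the 12 arrays stood for a gene, which gave 6976 genes.

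The tests used R 4.3.3 and limma 3.58.1. A linear model with 6 group means was fitted to all 12 arrays with lmFit, contrasts.fit and eBayes (no trend, not robust), leaving 6 residual degrees of freedom with 3.38 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over the 9641 probe sets of a comparison and a threshold of 0.05. The comparisons were IL-6 against PBS in control and in Socs3-deleted mice, the difference between these responses, IFN-γ against PBS in Ifng-null mice, Socs3-deleted against control mice after PBS and after IL-6, and Ifng-null against control mice after PBS. Fold changes are of means of log2 values, and the quoted group levels are arithmetic means of the deposited intensities. Socs3 was also compared over 4 against 4 arrays with an exact two-sided permutation test.

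Before the data were examined, 24 gene lists were fixed, covering liver functions, cytokine responses and markers of other cell types. They were tested with limma's camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison. The probe sets called higher after IFN-γ formed a further set. The rule for named genes, also fixed then, takes Socs3 and Ifng, then per comparison the 10 largest rises and 10 largest falls among called genes with 1 symbol whose groups do not overlap. It adds per list up to 4 called members, or up to 2 members where none was called. Genes that a count of 5 or fewer covers are also named. The pancreatic and haemoglobin genes were followed array by array after their values were seen.

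The code was tested on simulated data with 200 changed probe sets in each of 10 runs. For the IL-6 response in control mice it recovered 37.0%, 72.2% and 90.6% of 1.5-fold, 2-fold and 4-fold changes, and 5.87% of calls were false. For the difference between the IL-6 responses it recovered 8.36%, 46.1% and 77.0%, and 4.80% of calls were false. A list shifted by 1 on the log2 scale was called in 10 of 10 runs and other lists in 2 of 230 tests. The simulated probe sets were independent of each other, while acute phase genes had an estimated correlation of 0.36 in the data. These runs therefore do not show how often camera calls a list falsely when its members are correlated. The changed probe sets were drawn at random, each with its own residual SD, while genes that respond to IL-6 can be noisier. In control mice the SE of the log2 change after IL-6 was 0.67 for Lcn2 and 1.02 for Mt1. The recovered shares may therefore overstate the power for such genes.

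The alternatives fixed before the data were examined were quantile normalization, other floors and filters, an intensity trend, array weights, only the arrays compared, the replicate number as a block and leaving out each array. Added after seeing the data were no floor, leaving out the 2 arrays with high pancreatic enzyme signal, a haemoglobin covariate, a crossed replicate block and the tests of the IL-6 response of Socs3-deleted and of control mice against the IFN-γ response. Where leaving out an array leaves 1 in a group, that array is assumed to vary like the other groups.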

Results

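Liver RNA was measured on 12 Affymetrix mouse arrays, in 6 groups of 2, from mice killed 4 h after an intraperitoneal injection. Control mice carried a floxed Socs3 allele and no albumin-Cre, and received phosphate-buffered saline (PBS) or interleukin-6 (IL-6). Socs3-deleted mice carried 1 null and 1 floxed Socs3 allele with albumin-Cre, a recombinase driven by a hepatocyte promoter, and received the same injections. Mice without Ifng, the gene of interferon-gamma (IFN-γ), received PBS or IFN-γ. Each array gave a signal intensity for 12488 probe sets, and the median intensity per array lay between 80.6 and 85.7. The replicates of a group correlated across probe sets with Pearson's r from 0.977 to 0.987, and the SD of their log2 differences was 0.24 to 0.33. The labels do not say that the replicates were separate mice, so the p-values measure only the spread between these arrays. Whether it is a spread between mice is not known, and 2 arrays per group limit the precision of every value. Control and Socs3-deleted mice after PBS have values that argue against repeats of 1 RNA sample. The pancreatic enzyme gene Prss2 read 24.5 and 651 on the control arrays and 27.0 and 1863 on the Socs3-deleted arrays, and other such genes also differed. For the other groups technical repeats stay open. With 2 arrays against 2, an exact two-sided permutation test cannot give a p below 0.333, so single genes were tested with limma, which pools the spread over the 6 groups.

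Socs3, the gene of a feedback inhibitor of cytokine receptors, was lower in the arrays of Socs3-deleted mice than in those of control mice, on both of its probe sets. On the brighter probe set the intensity was 85.3 ± 14.3 (SD, n = 4) in Socs3-deleted and 137 ± 22.2 (SD, n = 4) in control mice. The highest Socs3-deleted array read 106 and the lowest control array 117. On the dimmer probe set the intensities were 59.7 ± 6.66 and 94.3 ± 14.6 (SD, n = 4 each). The levels were 1.61-fold and 1.57-fold lower. An exact two-sided permutation test over the 70 splits of 4 against 4 gave p = 0.0286 for each probe set. This is the smallest p it can give. The splits mixed PBS and IL-6 arrays freely, so the test ignores the injection. Splits within each injection, which are fewer, were not run. By group, the brighter probe set read 121 ± 4.38 in control mice after PBS and 153 ± 19.9 after IL-6, 75.6 ± 1.74 in Socs3-deleted mice after PBS and 95.0 ± 15.2 after IL-6, and 139 ± 34.8 and 132 ± 2.21 in Ifng-null mice after PBS and IFN-γ (SD, n = 2 each). By limma Socs3 passed the threshold in no comparison: the adjusted p between genotypes was 0.59 after PBS and 0.149 after IL-6 for the brighter probe set, and 0.772 and 0.0863 for the dimmer. Of 24 alternative settings, array weights alone took the brighter probe set past the threshold, after IL-6 (limma adjusted p = 0.0452). The log2 change of the brighter probe set was 0.34 after IL-6 in control mice, 0.32 in Socs3-deleted mice, -0.02 for the difference between these responses, -0.05 after IFN-γ and 0.18 between Ifng-null and control mice after PBS. Whether either probe set lies in the deleted part of the gene is not given in the sources used here. The Ifng probe set read at most 7.81 on any array, below the floor of 33.0, so it does not check the Ifng-null label.

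**Figure D1:**
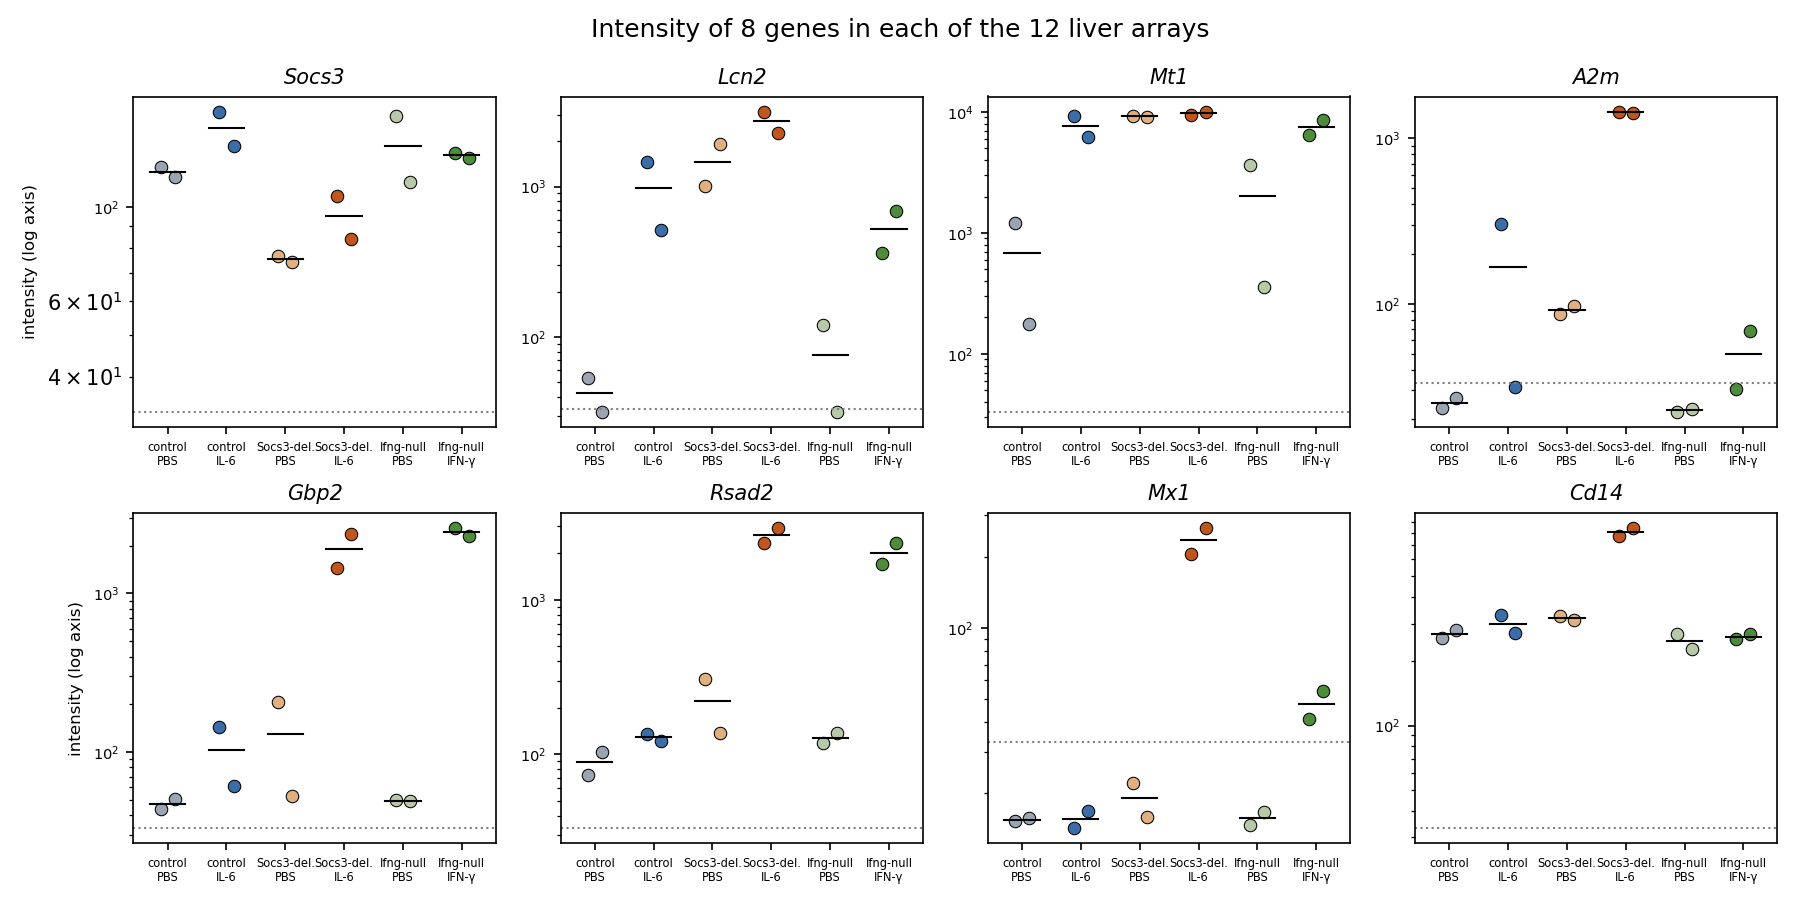
Intensity (log axis) of 8 genes on each of the 12 arrays, with a point per array, a bar at the mean of each group of 2 and a dotted line at the floor of 33.0. Mx1 read 235 on average in Socs3-deleted mice after IL-6 and 15.6 in control mice after IL-6, and Socs3 read 75.6 in Socs3-deleted and 121 in control mice after PBS.

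The IFN-γ injection of Ifng-null mice shows which liver genes this cytokine raised. Gbp2, which encodes an interferon-induced guanylate-binding GTPase, rose 49.5-fold, from 49.3 ± 0.332 to 2444 ± 207 (SD, n = 2; limma adjusted p = 0.00227). Cxcl9, a chemokine that attracts T cells, rose 47.6-fold, from 36.3 ± 0.332 to 1729 ± 59.4 (SD, n = 2; limma adjusted p = 0.00173). Samhd1, a dNTP hydrolase that restricts viruses, rose 19.6-fold and Igtp, an immunity-related GTPase, 17.6-fold. The other genes with the largest rises were Gm9706, Rsad2, Ifi47, Gbp7, Gbp3 and Ifit3, with log2 changes of 4.16, 3.97, 3.89, 3.17, 2.97 and 2.78. The 4 probe sets that fell were those of Fam107b (log2 change -1.12), Tbcel (-0.88), Paqr7 (-0.67) and Vcl, the gene of the adhesion protein vinculin (-0.67, with its other probe set at -0.19 and not past the threshold). Of 32 measured genes on the list of IFN-γ-inducible genes, 19 rose and none fell, 23 rose when adjusted over the list alone, and the median log2 change was 1.47. Of 20 type I interferon-inducible genes, 8 rose, among them Cmpk2 (2.66) and Usp18 (2.55), 15 rose adjusted over the list alone, and the median was 1.13. By limma's camera test these 2 lists rose with adjusted p = 8.23e-54 and 3.20e-33, and with adjusted p = 0.00499 and 0.0115 with an estimated correlation. Of 15 hepatocyte markers none had a positive change and none passed, with a median of -0.24 (limma camera adjusted p = 0.00087, and adjusted p = 0.202 with an estimated correlation). Of 21 chemokines and cytokines, 3 rose and 4 adjusted over the list alone: Cxcl9, Ccl2 (at least 4.52-fold) and Cxcl10 (at least 3.43-fold), the last 2 being at the floor in both PBS arrays. The camera test of limma gave this list adjusted p = 1.74e-05, and adjusted p = 0.167 with an estimated correlation. Of 27 acute phase genes 24 were positive and none passed, 3 rose adjusted over the list alone, and the median was 0.22. Of 29 STAT3-linked and immediate-early regulators 22 were positive and none passed, 4 rose adjusted over the list alone, and the median was 0.27. Their limma camera adjusted p was 4.21e-08 and 9.96e-08, and with an estimated correlation adjusted p = 0.35 and 0.253. Of 20 genes of cholesterol and fatty acid synthesis 1 had a positive change and none passed, with a median log2 change of -0.45 and limma camera adjusted p = 0.000949, or adjusted p = 0.494 with an estimated correlation. In all, limma called 63 of 9641 probe sets, 59 higher and 4 lower. Left out singly, IFN_PBS replicate 1, IFN_PBS replicate 2 and IFN_IFN replicate 2 gave 20, 20 and 22 calls; the count was 12 with the floor at the 50th percentile, 8 with no filter, 10 with only the arrays compared and 28 with array weights. Without the 2 arrays with high pancreatic enzyme signal, a setting chosen after seeing the data, it was 19. The call held in 7 of 24 alternative settings for Ifit3, 10 for Gm9706, 13 for Vcl and 15 for Ifi47, and in 10 of 23 for Cxcl10.

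In control mice, the IL-6 response asks how a liver with Socs3 reacts to this cytokine, and no probe set passed the threshold. Lcn2, which encodes an iron-scavenging acute phase protein, read 42.6 ± 15.5 after PBS and 984 ± 665 after IL-6 (SD, n = 2), a log2 change of 4.36 ± 0.67 (SE; limma adjusted p = 0.418), while its dimmer probe set gave 0.12. The metallothionein gene Mt1, which encodes a metal-binding stress protein, read 686 ± 722 and 7726 ± 2218 (SD, n = 2; limma adjusted p = 0.859). The early growth response gene Egr1 had a log2 change of -1.84 (limma adjusted p = 0.602), which lay between -2.42 and -1.26 over 24 alternative settings. G6pc, the gene of the last enzyme of glucose release, read 1640 after PBS and 662 after IL-6. Of 27 acute phase genes 26 had a positive change with a median log2 change of 0.84; 0 passed over all probe sets and 17 were higher adjusted over the list alone. The camera test of limma gave this list adjusted p = 6.38e-40, and adjusted p = 0.0776 with an estimated correlation. For the IFN-γ-inducible list 26 of 32 changes were positive (Ifi47 1.85, Igtp 1.56), with a median of 0.29, 0 calls and 6 adjusted over the list alone. For the type I list 18 of 20 were positive (Isg15 2.03), with a median of 0.24 and 0 calls by either adjustment. WT_IL6 replicate 1 read higher than replicate 2 for Isg15 (1635 and 299), Igtp (551 and 184) and Ifi47 (948 and 285). Without replicate 1 their log2 changes were 0.80, 0.77 and 0.99. Without replicate 2 they were 3.26, 2.35 and 2.72, and Isg15 and Igtp passed (limma adjusted p = 0.0121 and 0.0326). The limma camera adjusted p of the IFN-γ-inducible and type I lists was 1.49e-12 and 6.73e-10, and with an estimated correlation adjusted p = 0.114 and 0.153. By limma 0 probe sets passed and 248 had an unadjusted p under 0.05, against 482 expected by chance; the smallest adjusted p was 0.17. Without WT_IL6 replicate 2 the count was 8, with the floor at the 50th percentile it was 1, and without the 2 arrays with high pancreatic enzyme signal it was 0.

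The same injection in Socs3-deleted mice raised interferon-inducible genes. Gbp2 rose 17.8-fold, from 130 ± 108 to 1918 ± 656, and Rsad2, which encodes an antiviral radical-SAM enzyme, 12.7-fold, from 222 ± 120 to 2628 ± 432 (SD, n = 2; limma adjusted p = 0.00917 and 0.0012). A2m, the gene of the protease inhibitor alpha-2-macroglobulin, rose 15.7-fold, from 91.8 ± 7.06 to 1437 ± 22.0 (SD, n = 2; limma adjusted p = 0.0496). Mx1, an antiviral GTPase, was at the floor in both PBS arrays and rose at least 7.05-fold (limma adjusted p = 9.23e-05). The other large rises were those of Gm9706, Ifit3, Cxcl9, Isg15, Ifit2 and Gbp3, with log2 changes of 3.97, 3.36, 3.28, 3.27, 3.14 and 2.81. Genes that fell included Slc25a15, the mitochondrial ornithine carrier, from 2006 to 1010 (limma adjusted p = 0.00121), and Gpam, which starts triglyceride synthesis, from 647 to 291 (limma adjusted p = 0.0246). The remaining named falls were Cpeb2 (log2 change -1.63), Mcm10 (-1.39), Rora (-1.20), Vcl (-0.69), Klf9 (-0.62), Hpd (-0.57) and Pycrl (-0.55). The other probe sets of Rora, Vcl and Klf9 gave 0.00, -0.06 and -0.40 and did not pass.

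Among gene groups in Socs3-deleted mice, 11 of 20 type I interferon-inducible genes rose after IL-6 and 17 adjusted over the list alone, with a median log2 change of 1.67. Of 32 IFN-γ-inducible genes 12 rose, among them Gbp7 (2.74), and 16 adjusted over the list alone, with a median of 0.50. These lists rose by limma's camera test with adjusted p = 3.65e-30 and 5.37e-19, and with adjusted p = 0.0291 and 0.0422 with an estimated correlation. Of 27 acute phase genes, 1 rose (A2m) and 3 adjusted over the list alone; the median was 0.13, with limma camera adjusted p = 0.0066 and adjusted p = 0.678 with an estimated correlation. Lcn2 had a log2 change of 0.96 (limma adjusted p = 0.749), and of 0.295 on its dimmer probe set. Of 29 STAT3-linked and immediate-early regulators 1 rose, the NF-kappaB cofactor gene Bcl3, from 674 to 1650, and 5 adjusted over the list alone, with a median of 0.51. Of 15 macrophage and Kupffer cell markers 1 rose, the lipopolysaccharide co-receptor gene Cd14, from 319 ± 10.8 to 808 ± 47.8 (SD, n = 2; limma adjusted p = 0.00121), and the median was 0.15. Of 15 hepatocyte markers 1 fell, the tyrosine-catabolism gene Hpd, 3 fell adjusted over the list alone, no change was positive and the median was -0.18. The limma camera adjusted p of the regulator, macrophage and hepatocyte lists was 5.10e-07, 0.0066 and 0.000248, and with an estimated correlation adjusted p = 0.363, 0.435 and 0.182. Cxcl9 rose among 21 chemokines and cytokines (limma camera adjusted p = 0.0159, and adjusted p = 0.435 with an estimated correlation), and Gpam fell among 20 genes of cholesterol and fatty acid synthesis (median -0.08, limma camera adjusted p = 0.195).

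In the other lists no member passed over all probe sets after IL-6 in Socs3-deleted mice on the probe set that stands for its gene. Of the endothelial markers 1 rose adjusted over the list alone. Tie1, an endothelial receptor kinase gene, had a log2 change of 0.67 on that probe set (limma adjusted p = 0.0955) and rose by 1.27 on its other probe set (limma adjusted p = 0.00414). Median log2 changes were 0.08 for 8 MHC class I genes, 0.10 for 10 MHC class II genes, where Cd74 had a log2 change of 0.79 (limma adjusted p = 0.625) that was -0.014 without S3_IL6 replicate 1, 0.05 for 12 neutrophil, 0.07 for 12 T and NK cell and 0.08 for 10 B cell markers. They were -0.02 for 10 erythroid, -0.04 for 13 stellate cell and fibroblast and 0.03 for 11 endothelial markers, and 0.07 for 14 heat shock and stress genes. Medians of -0.01 for 14 circadian clock, -0.06 for 11 sex-biased and -0.19 for 19 fatty acid oxidation genes, and of -0.25 for 29 cytochrome P450 enzymes, had limma camera adjusted p of 0.58, 0.58, 0.392 and 0.0636. Of 28 genes of complement and coagulation 7 were positive with a median of -0.18 (limma camera adjusted p = 0.0066, and adjusted p = 0.678 with an estimated correlation). Of 17 genes of gluconeogenesis and glucose control 1 fell adjusted over the list alone and the median was -0.19 (limma camera adjusted p = 0.0321, and adjusted p = 0.435 with an estimated correlation); G6pc had a log2 change of -2.07 (limma adjusted p = 0.0762), read 533 and 187 on the IL-6 arrays and passed in 2 of 24 alternative settings. Without S3_IL6 replicate 1 its log2 change was -2.83 (limma adjusted p = 0.0161) and without S3_IL6 replicate 2 it was -1.32.

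By limma 113 probe sets changed after IL-6 in Socs3-deleted mice, 99 higher and 14 lower. The count was 55, 34 and 33 without S3_PBS replicate 1, S3_PBS replicate 2 and S3_IL6 replicate 2, 42 with the floor at the 50th percentile, 28 with no filter and 1 with only the arrays compared. Without the 2 arrays with high pancreatic enzyme signal, a setting chosen after seeing the data, 9 probe sets were called. A2m held its call in 9 of 24 alternative settings, Isg15 in 8, Gm9706 in 10 and Rsad2 in 23, and among the falls Hpd held in 4, Pycrl in 5, Klf9 in 6 and Mcm10 in 11.

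The difference between the IL-6 responses of Socs3-deleted and control mice was tested directly. It was larger in Socs3-deleted mice for 4 genes, each of which is interferon-inducible: Ifit2 by 3.14 ± 0.27, Mx1 by 2.82 ± 0.21, Cmpk2 by 2.57 ± 0.25 and Gbp3 by 2.22 ± 0.27 on the log2 scale (SE; limma adjusted p = 0.00347, 0.00213, 0.00585 and 0.0292). Cmpk2, a mitochondrial nucleotide kinase gene, read 44.4 and 47.8 in control mice and 51.1 and 323 in Socs3-deleted mice after PBS and IL-6; Gbp3 read 80.8 and 124, and 108 and 747. The call held in 19 of 24 alternative settings for Ifit2, 23 for Mx1, 18 for Cmpk2 and 9 for Gbp3. Ifit2 and Mx1 were at the floor in all 4 control arrays, and Mx1 also in Socs3-deleted mice after PBS. Arrays set to the floor show no spread, so the SE and limma p of these 2 genes may be too small. Type I interferon-inducible genes had 3 calls and 9 adjusted over the list alone among 20, with a median difference of 1.32 (limma camera adjusted p = 5.55e-23, and adjusted p = 0.0589 with an estimated correlation). Macrophage and Kupffer cell markers had 12 positive differences among 15 and a median of 0.16, and hepatocyte markers 3 among 15 and a median of -0.20. Their limma camera adjusted p was 0.00445 and 0.00312, and with an estimated correlation adjusted p = 0.532 and 0.377. The IFN-γ-inducible list had 1 call and 5 adjusted over the list alone, with a median of 0.25 (limma camera adjusted p = 1.61e-09, and adjusted p = 0.21 with an estimated correlation). Acute phase genes had no call, 4 positive differences among 27 and a median of -0.61 (limma camera adjusted p = 8.68e-09, and adjusted p = 0.463 with an estimated correlation), with Mt1 at -3.96 and Lcn2 at -3.41 (limma adjusted p = 0.999 and 0.74); the dimmer Lcn2 probe set had the opposite sign, at 0.18. Egr1 at 2.42 and Cd14 at 1.19 did not pass either (limma adjusted p = 0.453 and 0.0883). Between genotypes, Socs3-deleted against control, the acute phase median was 1.03 after PBS, with 25 of 27 positive. After IL-6 it was 0.28, with 22 positive, and no member was called in either. The negative acute phase differences thus go with higher levels in Socs3-deleted mice after PBS, not with lower levels after IL-6. Some members already read high on the Socs3-deleted PBS arrays, whose highest values were 14466 and 14251. Hp read 11753 and 13365 there and Mt1 9266 and 9157, while others such as Lcn2, at 1006 and 1907, were far lower. Whether the upper end of the intensity scale limited the measured rise of the bright members was not tested. In all limma called 4 probe sets. The count was 1, 1, 12, 2, 7 and 15 without WT_PBS replicate 1, WT_PBS replicate 2, WT_IL6 replicate 1, WT_IL6 replicate 2, S3_PBS replicate 1 and S3_IL6 replicate 1, 13 with the floor at the 50th percentile and 1 with only the arrays compared. Without the 2 arrays with high pancreatic enzyme signal, chosen after seeing the data, limma called 0. The differences of Ifit2, Mx1, Cmpk2 and Gbp3 were then 2.82, 2.82, 2.32 and 1.96 (limma adjusted p = 0.0916, 0.145, 0.187 and 0.43).

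The 59 probe sets that IFN-γ raised in Ifng-null mice were then followed through the IL-6 responses, whose arrays are different ones. After IL-6 their median log2 change was 1.21 in Socs3-deleted mice, with 58 positive and 35 called higher, and 0.49 in control mice, with 54 positive and 0 called. The median of the difference between the responses was 0.79, with 55 of 59 positive and 3 called. By limma's camera test the adjusted p was 1.04e-68, 4.59e-39 and 2.81e-38, and with an estimated correlation adjusted p = 0.00325, 0.00811 and 0.00811. With 1 array left out, the control median ranged from 0.28 (without WT_IL6 replicate 1) to 0.64 (without WT_IL6 replicate 2). The median of the difference ranged from 0.52 (without WT_IL6 replicate 2) to 0.84 (without S3_IL6 replicate 1). The 35 shared probe sets compare with 0.606 expected of independent lists of 59 and 99 (Fisher's exact test, p = 5.21e-57), and Vcl was the 1 shared gene that fell. That test takes probe sets as independent, which genes that change together are not. Both lists also share 1 estimate of spread per probe set, so the Fisher p only describes the overlap. Across probe sets, which are not independent replicates, the log2 changes after IFN-γ correlated with those after IL-6 with r = 0.587 and rho = 0.439 in Socs3-deleted mice, and r = 0.455 and rho = 0.228 in control mice.

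**Figure D2:**
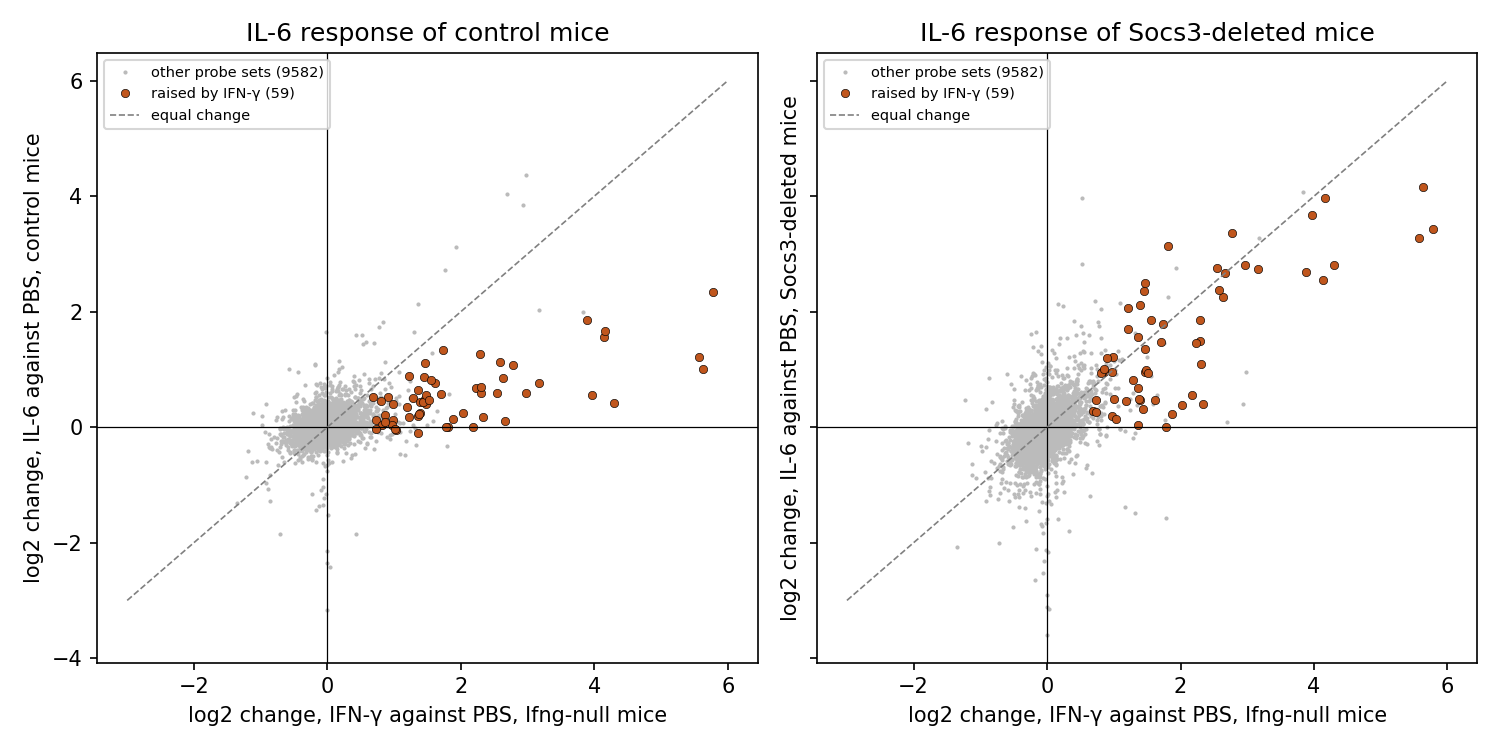
Log2 change after IL-6 in control (left) and Socs3-deleted (right) mice against log2 change after IFN-γ in Ifng-null mice, a point per probe set, with the 59 probe sets raised by IFN-γ in colour and a dashed line of equal change. The coloured points have a median of 0.49 on the left and 1.21 on the right.

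Socs3-deleted mice were compared with control mice after PBS for the effect of the genotype without cytokine, and no probe set passed the threshold. Lcn2 read 1457 ± 638 against 42.6 ± 15.5 (SD, n = 2), a log2 difference of 5.04 ± 0.67 (SE; limma adjusted p = 0.104), while its dimmer probe set had the opposite sign, at -0.11. Mt1 differed by 4.33 and Egr1 by -1.59 (limma adjusted p = 0.502 and 0.523), and the neutrophil chemokine gene Cxcl1 by 2.76 (limma adjusted p = 0.951). Egr1 read 326 and 728 on the 2 control arrays, and its difference lay between -2.17 and -0.87 over 24 alternative settings. Of 27 acute phase genes 25 had a positive difference with a median of 1.03; 0 passed over all probe sets and 18 were higher adjusted over the list alone (limma camera adjusted p = 5.24e-28, and adjusted p = 0.182 with an estimated correlation). All 20 type I interferon-inducible genes were positive with a median of 0.28 and no call (limma camera adjusted p = 7.33e-05, and adjusted p = 0.367 with an estimated correlation). Of 15 macrophage and Kupffer cell markers 13 were positive with a median of 0.16 (limma camera adjusted p = 0.00451, and adjusted p = 0.431 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase gene, read 535 against 1230 (limma adjusted p = 0.3, and 0.0149 without S3_PBS replicate 2), the peroxisomal thiolase gene Acaa1b had a log2 difference of -0.84 (limma adjusted p = 0.331) and the glucose transporter gene Slc2a2 of -1.05 (limma adjusted p = 0.547). By limma 0 probe sets passed and 402 had an unadjusted p under 0.05, against 482 expected by chance. Without S3_PBS replicate 1 the count was 8 and without S3_PBS replicate 2 it was 3; without both arrays with high pancreatic enzyme signal it was 0.

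**Figure D3:**
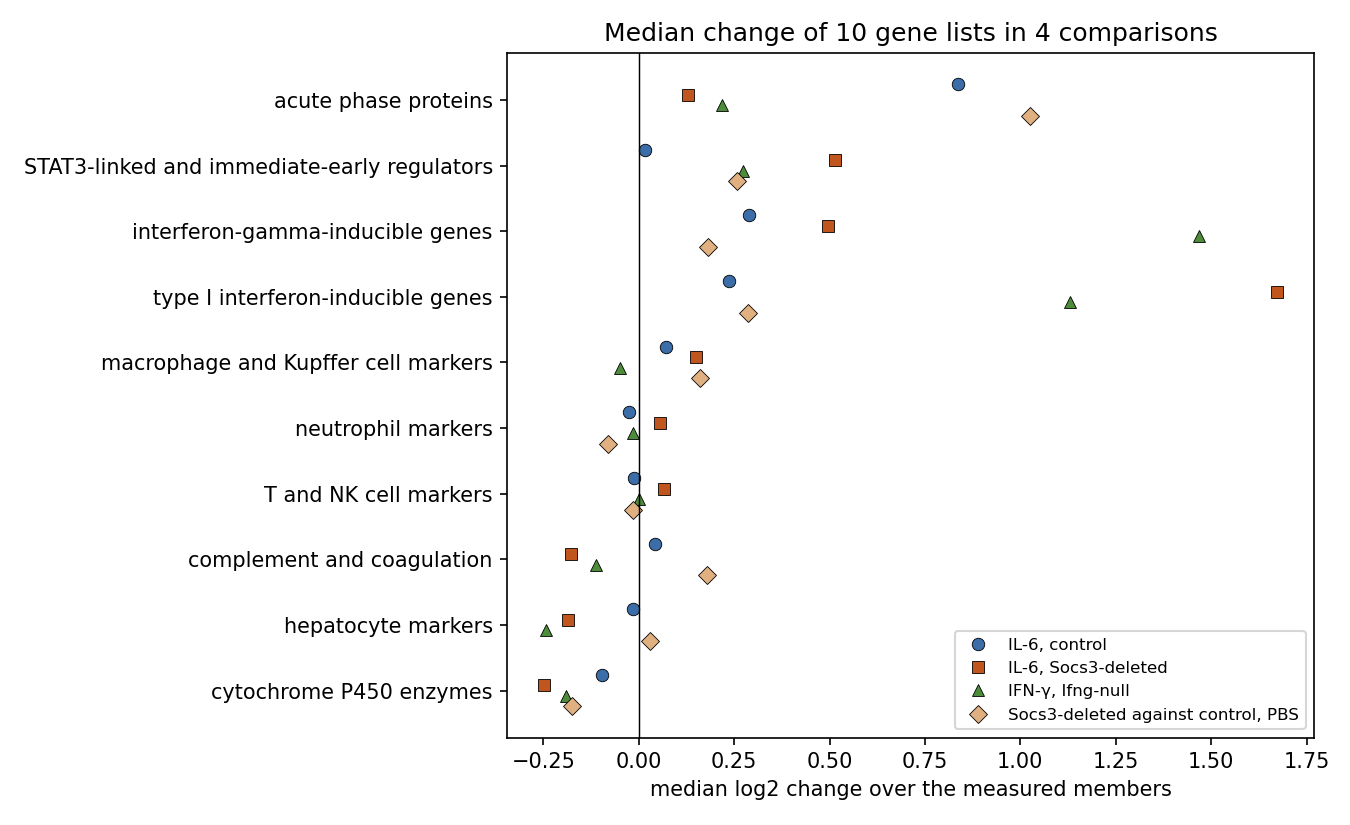
Median log2 change over the measured members of 10 gene lists in 4 comparisons, a marker per comparison. Acute phase genes had medians of 0.84 after IL-6 in control mice and 1.03 between genotypes after PBS, and type I interferon-inducible genes a median of 1.67 after IL-6 in Socs3-deleted mice.

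After IL-6, Socs3-deleted mice had higher interferon-inducible transcripts than control mice. Rsad2 was 20.3-fold higher, at 2628 ± 432 against 129 ± 10.3, and Gbp2 19.8-fold, at 1918 ± 656 against 103 ± 58.6 (SD, n = 2; limma adjusted p = 0.000536 and 0.0136). Ifit2 was higher by at least 3.46 and Mx1 by at least 2.82 on the log2 scale, both being at the floor in control mice. Gadd45g, a growth arrest gene, was 7.20-fold higher, at 1066 against 140, and Cebpd, a transcription factor gene of the acute phase, 4.86-fold, at 776 against 159 (limma adjusted p = 0.0255 and 0.0194). Other named genes with higher levels were Cxcl9, Ifit3, Cmpk2, Samhd1 and Gbp3, with log2 differences of 3.18, 3.16, 2.76, 2.65 and 2.62. Lower in Socs3-deleted mice were the lipid droplet gene Plin2, at 1802 against 3490 (limma adjusted p = 0.0341), the cholesterol transport gene Npc1 (-1.06), Gpam (-1.18), Rora (-0.95, its other probe set 0.02), Vcl (-0.69, its other probe set -0.24), Pycrl (-0.56) and Slc25a15 (-0.55). Of 20 type I interferon-inducible genes 8 were higher and 15 adjusted over the list alone, with a median of 1.51; of 32 IFN-γ-inducible genes 8, among them Gbp7 (2.15), and 15, with a median of 0.46. By limma camera the adjusted p was 5.69e-32 and 5.88e-18, and with an estimated correlation adjusted p = 0.0249 and 0.0486. Of 29 STAT3-linked and immediate-early regulators 4 were higher, Gadd45g, Cebpd, the oncostatin M receptor gene Osmr (1.13) and Bcl3 (1.06), and 12 adjusted over the list alone. Of 15 macrophage and Kupffer cell markers Cd14 was higher, 2.71-fold, 3 adjusted over the list alone, and the median was 0.43. Of 19 genes of fatty acid oxidation Plin2 was lower, 2 adjusted over the list alone, and the median was -0.42. The limma camera adjusted p of these 3 lists was 1.09e-12, 1.70e-07 and 1.63e-05, and adjusted p = 0.115 with an estimated correlation for each. Of 15 hepatocyte markers 1 had a positive difference and the median was -0.17 (limma camera adjusted p = 0.00264, and adjusted p = 0.195 with an estimated correlation). The endothelial gene Tie1 was higher by 1.65 on 1 probe set (limma adjusted p = 0.000868) and read 0.71 on the other (limma adjusted p = 0.0865). Acute phase genes had no call, 22 positive differences among 27 and a median of 0.28 (limma camera adjusted p = 4.34e-05, and adjusted p = 0.421 with an estimated correlation). In all limma called 92 probe sets, 83 higher and 9 lower. The count was 54, 13 and 25 without WT_IL6 replicate 1, WT_IL6 replicate 2 and S3_IL6 replicate 2, 50 without either WT_PBS array and 46 without either IFN_PBS array; it was 35 with the floor at the 50th percentile, 22 with no filter, 0 with only the arrays compared and 223 with array weights. Without the 2 arrays with high pancreatic enzyme signal, chosen after seeing the data, it was 35. The call held in 2 of 24 alternative settings for Pycrl, 7 for Bcl3, 9 for Rora and 10 for Slc25a15, and in 12 of 23 for Osmr.

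Ifng-null and control mice after PBS were compared for the baseline of the IFN-γ experiment, and the labels do not say whether they share a strain background. No probe set passed the threshold. Egr1 had a log2 difference of -1.55, Mt1 of 1.32, Hba-a1, a haemoglobin gene, of -2.15 and Plin2 of 0.69 (limma adjusted p = 0.873 for each). Of 20 type I interferon-inducible genes 17 had a positive difference with a median of 0.34 (limma camera adjusted p = 0.00109, and adjusted p = 0.688 with an estimated correlation). Of 19 genes of fatty acid oxidation 17 were positive with a median of 0.22 and 1 higher adjusted over the list alone (limma camera adjusted p = 0.0033, and adjusted p = 0.688 with an estimated correlation). By limma 0 probe sets passed and 297 had an unadjusted p under 0.05, against 482 expected by chance. Mt1 read -0.065 and Hba-a1 0.023 without WT_PBS replicate 2, and Mt1 read -0.36 and Socs3 -0.080 without IFN_PBS replicate 1. The Egr1 difference lay between -2.13 and -0.97 over 24 alternative settings.

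Genes of the exocrine pancreas stood apart on 2 arrays, WT_PBS replicate 2 and S3_PBS replicate 2. The trypsinogen gene Prss2 read 651 and 1863 on these arrays and 22.4 to 27.3 on the other 10. The chymotrypsinogen gene Ctrb1 read 2753 and 5021 against 217 to 324, the elastase genes Cela1 2694 and 5931 against 454 to 873 and Cela2a 726 and 1758 against 138 to 179, and Reg1 701 and 2400 against 76.4 to 112. Over 7 pancreas and gut markers the median log2 change after IL-6 was -1.35 in control mice (limma camera adjusted p = 0.115) and -1.71 in Socs3-deleted mice (limma camera adjusted p = 0.0148, and adjusted p = 0.435 with an estimated correlation), with no member past the threshold. Haemoglobin transcripts varied within groups: Hba-a1 read 6389 and 4864 on the same 2 arrays and 294 to 3649 on the others, and Hbb-b2 757 and 527 against 22.9 to 393. Hbb-b2 read higher on replicate 2 than on replicate 1 in every group, and Hba-a1 in every group but Ifng-null mice after PBS.

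**Figure D4:**
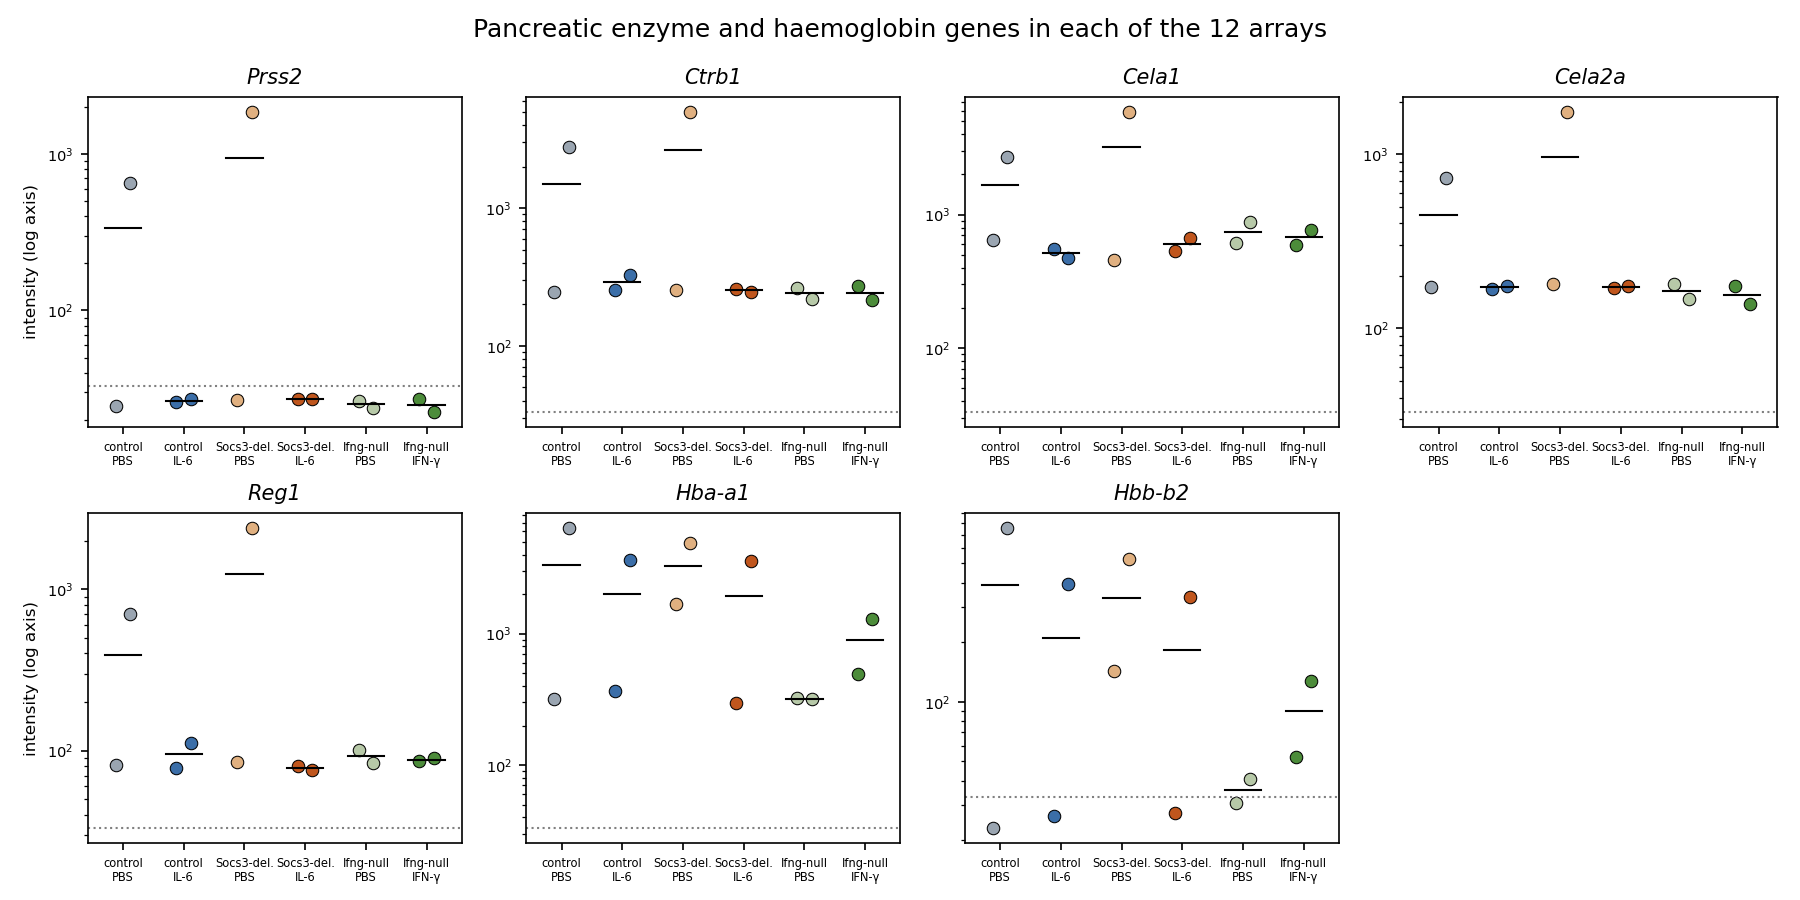
Intensity (log axis) of 5 pancreatic enzyme genes and 2 haemoglobin genes on each of the 12 arrays, with a point per array, a bar at the mean of each group of 2 and a dotted line at the floor of 33.0. Prss2 read 651 and 1863 on 1 control and 1 Socs3-deleted array after PBS, and at most 27.3 on the other 10.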

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

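Each of the 4 tests of explanations in this part was chosen only after the result was seen. The IL-6 response differed between Socs3-deleted and control mice, by limma's test of the difference itself, for Ifit2 (log2 difference 3.14), Mx1 (2.82), Cmpk2 (2.57) and Gbp3 (2.22), and the 59 probe sets raised by IFN-γ had a median difference of 0.79.

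The pattern is a stronger interferon-type response to IL-6 in Socs3-deleted mice. More macrophages would raise their markers as far as the set: in the IL-6 response of Socs3-deleted mice the upper quartile of the macrophage list (0.38) lay below the lower quartile of the set (0.49), which argues against it there, but in the difference between the responses it did not (0.37 against 0.28), so a contribution to the difference stays open. One weakly responding control array would let the stronger control array reach the Socs3-deleted arrays, but the lower Socs3-deleted array lay 1.05 above the higher control array in mean log2 level of the set, against ranges of 0.10 and 0.46 within the groups, and 53 of 59 members were higher on both Socs3-deleted than on both control arrays. IFN-γ made in the animal after IL-6 may account for the pattern and stays open, because the Ifng probe set read at most 7.81 on any array, below the floor of 33.0, and so decides nothing. A direct effect of the Socs3 deletion in hepatocytes stays open too, as a hypothesis that these data do not separate from it.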

How the results depend on the processing

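Settings added after seeing the data were no floor, leaving out the 2 arrays with high pancreatic enzyme signal, the haemoglobin covariate and the crossed block. Counts of called probe sets are given for IL-6 in Socs3-deleted mice, the difference between the IL-6 responses, IFN-γ, and genotypes after IL-6, in this order. They were 42, 13, 12 and 35 with the floor at the 50th percentile (and 1 for IL-6 in control mice), and 9, 0, 19 and 35 without the pancreatic arrays. With only the arrays compared they were 1, 1, 10 and 0, fewer arrays leaving fewer degrees of freedom. With no filter they were 28 for IL-6 in Socs3-deleted mice, 8 for IFN-γ and 22 for genotypes after IL-6, and with array weights 28 and 223 for the last 2. The cause was not tested for the others. Leaving out 1 array gave 33 to 113, 1 to 15, 20 to 63 and 13 to 95, then 0 to 8 for IL-6 in control mice and for genotypes after PBS, and 0 for Ifng-null against control mice. The IFN-γ-induced set kept its direction and side of the threshold under all settings run. Its leave-one-out medians were 0.28 to 0.64 in control mice, 1.18 to 1.38 in Socs3-deleted mice and 0.52 to 0.84 for the difference. The trend and array weights do not enter its camera test. That test used the preset correlation of 0.01 throughout, against an estimated 0.25 for the set, and the estimated version was not run under these settings. Keeping its side of the threshold therefore says little, while the medians do show how far the effect moved.

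With the replicate block the counts were 123, 6, 60 and 104, and 0 for the other comparisons. The set medians were 0.49, 1.21 and 0.79. Each count was within 1.5 times the count without the block, and 4 of 105 calls or non-calls of named genes changed. The block was 1 replicate effect common to all 6 groups, so it could not take up an effect of the Ifng-null arrays alone. Replicate differences correlated at 0.14, 0.12 and 0.66 between the 2 groups of control, Socs3-deleted and Ifng-null mice, and at -0.25 to 0.31 between other groups. With 2 numbers per group this does not settle whether the numbers pair the samples; WT_PBS and IFN_PBS gave -0.11, and the crossed replicate block, run only for these 2 groups, left their comparison at 0 calls. Of 9172 probe sets 584 differed the same way in all 6 groups, against 287 by chance and 1163 for the highest other orientation of the numbers. The haemoglobin gene Hbb-b2 read higher on replicate 2 in every group.

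Values that changed sign, of which only the list was past its threshold, were Cd74 after IL-6 in Socs3-deleted mice (-0.014 without S3_IL6 replicate 1, up to 1.60 without S3_IL6 replicate 2) and the cholesterol list in the difference (median -0.23, limma camera adjusted p = 0.0391, and adjusted p = 0.714 with an estimated correlation; 0.13 without the pancreatic arrays). Socs3 in the difference read 0.018, 0.11, 0.00429 and 0.14 without WT_PBS replicate 2, WT_IL6 replicate 1, S3_PBS replicate 1 and S3_IL6 replicate 2, down to -0.18 without S3_IL6 replicate 1, and after IFN-γ 0.21 and -0.31 without IFN_PBS replicates 1 and 2 and 0.021 with the haemoglobin covariate. Between Ifng-null and control mice, Socs3 read -0.080 and 0.44 and Mt1 -0.36 and 2.99 without IFN_PBS replicates 1 and 2, Mt1 -0.065 and Hba-a1 0.023 without WT_PBS replicate 2 or without the pancreatic arrays, and Hba-a1 -4.31 without WT_PBS replicate 1 and 0 with the haemoglobin covariate, which is that gene itself. With an estimated correlation 6 of 50 list calls in the 7 comparisons held and 44 were lost. Signal near the floor limits what can be seen of dim genes.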

Other observations

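The tests of the acute phase pattern and the tests of the IL-6 against the IFN-γ response were chosen only after the results were seen, while those on the second pancreatic acinar list and the gut list were written before their values were examined, except that Fabp2 of the gut list had been seen.

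The IL-6 response of Socs3-deleted mice was set against the IFN-γ response of Ifng-null mice in the same limma fit, and limma called 2 genes. Mx1 had a log2 difference of 2.30, but it was at the floor in both PBS groups, so this is the difference between its levels after IL-6 and after IFN-γ; with no floor it was 2.04 and did not pass (limma adjusted p = 0.0546). Irf8, which encodes a transcription factor of myeloid cells, changed by 0.24 after IL-6 and rose by 1.88 after IFN-γ, a log2 difference of -1.64. The limma adjusted p of Mx1 and Irf8 was 0.0128 and 0.0148. Across 24 alternative settings Mx1 passed in 14 and Irf8 in 12. The count was 0 without WT_PBS replicate 1, WT_PBS replicate 2, S3_PBS replicate 2, S3_IL6 replicate 2 or IFN_PBS replicate 2, 1 without IFN_IFN replicate 2, 4 without either WT_IL6 array and 16 without S3_IL6 replicate 1. Under the other settings it was 0 to 11, with 0 both for only the arrays compared and without the pancreatic arrays. The list of 32 IFN-γ-inducible genes had a median difference of -0.40 (limma camera adjusted p = 1.21e-13, and adjusted p = 0.179 with an estimated correlation). Medians for 20 type I interferon-inducible genes, 15 macrophage and Kupffer cell markers and 7 pancreas and gut markers were 0.17, 0.21 and -1.64. Their limma camera adjusted p was 0.00265, 0.00608 and 0.00265, and adjusted p = 0.756 with an estimated correlation for each. The groups differ in genotype as well as in cytokine.

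The IL-6 response of control mice was set against the IFN-γ response in the same way, and limma called 5 probe sets, each with a smaller change after IL-6. They were those of Samhd1 (log2 difference -3.87), Irf8 (-1.74), Cmpk2 (-2.56) and Gbp3 (-2.38), with limma adjusted p = 0.00613 for the first 3 and 0.0162 for Gbp3, and 1 without a single gene symbol (-2.15). The call held in 20, 19, 18 and 12 of 24 alternative settings for the 4 genes. The IFN-γ-inducible and type I lists had median differences of -1.10 and -0.62, with limma camera adjusted p = 5.04e-44 and 1.20e-20, and adjusted p = 0.00879 and 0.0399 with an estimated correlation. Medians for acute phase genes, genes of cholesterol and fatty acid synthesis, hepatocyte markers and STAT3-linked regulators were 0.63, 0.57, 0.16 and -0.13. Their limma camera adjusted p was 7.79e-07, 7.39e-05, 0.0247 and 7.39e-05, and adjusted p = 0.39 with an estimated correlation for each. Chemokines and cytokines had a median of -0.16 (limma camera adjusted p = 8.08e-05, and adjusted p = 0.23 with an estimated correlation). The count of calls was 0 without either WT_PBS array, 8 and 2 without WT_IL6 replicates 1 and 2, 10 without either S3_PBS array, 3 without either S3_IL6 array and 13 without IFN_IFN replicate 1. It was 0 with no filter, 2 with the floor at the 50th percentile and 1 without the pancreatic arrays.

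Acute phase transcripts had positive differences between Socs3-deleted and control mice after PBS with no gene past the threshold (limma camera adjusted p = 5.24e-28 for the list, and adjusted p = 0.182 with an estimated correlation), and 22 of 27 members read above the other 4 PBS arrays on both Socs3-deleted arrays. An IL-6-injected Socs3-deleted liver under the PBS label would carry the IFN-γ-induced set at its IL-6 level, but the higher PBS array lay below the lower IL-6 array, at -1.40 in mean log2 level. Pancreatic material in 1 array of each group stays open: that array read above its partner in Socs3-deleted mice and below it in control mice (median log2 differences 0.22 and -0.47 over the list), and the Socs3-deleted array without it lay 0.62 above the highest of the 3 other PBS arrays without it, within their range of 0.69. Variation between PBS-injected mice may account for it too: 1 of the 15 splits of the 6 PBS arrays into 2 and 4, the real one, gave a difference as large (1.23, against 1.09 for the highest other), and 15 splits are too few for a share under 0.05. A genotype effect stays open as an untested hypothesis.

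Pancreatic enzyme transcripts on WT_PBS replicate 2 and S3_PBS replicate 2 may come from pancreatic tissue taken with the liver. Of 10 measured genes of a second acinar list of 17, the same 2 arrays were the highest of 12 for 9, where chance gives 1.52% per gene. For gut material the same held for 0 of 6 measured genes of a gut list of 12, which argues against gut material on both arrays. The criterion would miss gut material on only 1 of them. Tff3 of the gut list read 1709 and 781 on S3_PBS replicates 1 and 2, and 237 to 455 on the other 10 arrays. No biological explanation was tested, since each of the 2 arrays has a partner of its own group without the signal.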
